A study of Mus musculus with 11 samples.

How the data were processed

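Small RNA was sequenced from feces of C57BL/6 mice in 3 phases of colitis caused by dextran sulfate sodium (DSS), a polymer that injures the lining of the colon when it is drunk. The 11 libraries were 4 taken before DSS, 3 on day 5 of DSS and 4 on day 12, in the recovery phase. Per the labels' protocols, mice drank 2.5% DSS for 5 days and DSS-free water after that, for 13 days in the plan, so that the recovery samples followed 7 days without DSS. RNA came from feces homogenized in saline with a mirVana kit, libraries were made with the TruSeq small RNA kit, and sequencing was done on a HiSeq 2500 instrument, per the labels' protocols. The ACGT101-miR program removed adapter dimers, junk reads, low complexity reads, ribosomal, transfer, small nuclear and small nucleolar RNA and repeats, per the labels' protocols. The aligner, the miRNA reference release, the genome build and the allowed mismatches are not given in the sources used here. Removal of those RNA classes means that the counts say nothing about how much of the fecal RNA was miRNA.

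The authors deposited a table with a raw read count for each of 616 rows in each library, 544 with miRNA names and 72 numbered rows without one. The table's 11 other columns, scaled values for the same libraries, were not used, and the TPM values below were computed from the counts, as the count over the library's total in the table with no length term. Only the miRNA counts that passed the authors' filters are in the table, so its totals are miRNA totals and not sequencing depth. The totals ran from 11749 to 40835 counts per library. At these totals 3 counts correspond to between 73.5 and 255.3 CPM (the count scaled to a common library total, as edgeR gives it), so a miRNA below about that level could be missed in a single library. Confidence intervals and floors cover counting error only, since the reads carry no molecular identifiers.

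Groups were taken from the labels. The day 12 columns match sample titles by number. The day 5 columns carry the numbers 1, 3 and 4 while the titles number the samples from 1 to 3, and the before-DSS columns carry another day name than the titles, so both sets were assigned to their group only, the before-DSS set because no other group of 4 was left. The text names libraries by group and by the number in the deposited column. The labels do not say whether the libraries of a group come from separate mice, or whether the same mice were sampled in each phase, so p-values measure the spread between these samples, part of which may be technical. Counts of every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.71, so no library holds the same reads as another, but repeat preparations of 1 sample are not excluded. The labels' protocols name fewer libraries than the 11 samples they list.

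Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors) in R 4.3.3 with all 11 libraries in a fit on group, after edgeR's default filter on low counts, which kept 137 rows holding 94.1% to 98.2% of the counts of a library. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The TMM factors ran from 0.72 to 1.31. Fold changes are log2 values with standard errors taken from the F statistic. A fold against a group with no count was computed against a floor of 3 counts over the whole group. It takes the count of the other group as observed. The counting error of that count is left out, so such a fold is not a full lower bound. Where a group held 1 count, the ratio of pooled CPM is given with an exact 95% interval. The 18 miRNA lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, for lists with at least 3 tested members, which gave 27 tests adjusted together. Single values per library were compared with exact two-sided permutation tests in scipy 1.17.1. The smallest p that these can give is 0.0286 for 4 against 4 libraries and 0.0571 for 4 against 3. In the family of 24 composition tests no adjusted p under 0.05 can therefore be reached.

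The tests, the lists, the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule takes, per comparison, the 10 largest changes in each direction among miRNAs past the threshold, the smallest p-values up to 5 where fewer than 5 passed, the 10 most abundant miRNAs, miR-142a-3p always, and up to 4 members of each list by abundance. The alternatives were other scalings (RLE, TMMwsp, library total only), other filters on low counts (none, or at least 10 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, limma-trend on TPM with pseudocounts of 1, 0.1 and 10, a fit of only the groups compared, the column number as a replicate block, removal of the 5 most abundant miRNAs, and leaving out each library. Fits with fewer libraries kept the 137 rows. Added after the data were seen were merging rows with nearly equal counts, leaving out the numbered rows, leaving out before-DSS library 2 with recovery library 4, and leaving out each library in the list tests, with the preset and with an estimated correlation.

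Whether column numbers pair the libraries was checked from the correlation of their deviations from the group means. It was 0.15 to 0.51 over the 4 pairs of recovery and before-DSS libraries and 0.10 to 0.35 over the 3 pairs of recovery and day 5 libraries, above 0.1 in each pair, and -0.10 to 0.13 over the 3 pairs of day 5 and before-DSS libraries. The pairing rests on the numbers in the deposited column names and on these data, not on the labels, and 2 of the 4 and 2 of the 3 pairs correlated best with their own number. Blocked values stand beside the recovery comparisons where they changed a call or moved a count by over 1.5 times.

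The edgeR and camera steps were tested on 20 simulated data sets drawn from the real means and totals, with 128.5 rows tested in the median data set. Each miRNA was drawn independently, so the variation that miRNAs share across the real libraries was left out. In the simulated recovery against before-DSS comparison, 74.5% of miRNAs changed by a log2 of 2 and 92.5% of those changed by a log2 of 4 were recovered. Of the calls, 3.61% were false. A list of 6 raised members had a camera p under 0.05 in 100% of data sets, and an unchanged one in 5%. With the real libraries, 85 of the other random splits gave a list call, and 5 gave a miRNA call among the 3 phases. The simulated rates therefore need not hold for the real libraries. Hairpin positions come from the GENCODE M21 annotation of the mouse assembly GRCm38. The deposited table gives no positions.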

Results

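Fecal miRNAs were counted in 11 libraries from mice before DSS (n = 4), on day 5 of DSS, the acute phase of colitis (n = 3), and on day 12, after 7 days without DSS (n = 4). The question was how the fecal miRNA profile moved through acute inflammation and recovery. No library came from untreated mice on day 5 or 12, so differences between phases are also differences between sampling days. The total miRNA count was 23027 ± 7743 (SD, n = 4) before DSS, 14025 ± 3350 (SD, n = 3) on day 5 and 28166 ± 9250 (SD, n = 4) on day 12. The most abundant miRNA was miR-21a-5p, a miRNA of many inflamed and growing tissues, with a mean of 242137 CPM over the 11 libraries, followed by miR-148a-3p (122918 CPM) and miR-192-5p, an abundant miRNA of intestinal epithelium. The other members of the top 10 were let-7f-5p, miR-9-5p, miR-9b-3p, let-7i-5p, miR-378a-3p, miR-200b-3p and miR-194-5p. The hairpin of miR-21a lies on chromosome 11 at 86584067 to 86584158 in an exon of Vmp1.

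The first comparison, of day 5 with before DSS, asked which fecal miRNAs differed in acute colitis. No miRNA passed the threshold in edgeR's quasi-likelihood test of 137 miRNAs. At an unadjusted p under 0.05 there were 34, of which 18 had higher and 16 lower values on day 5. DESeq2 called 5 (4 higher and 1 lower), limma-voom 0, and limma-trend on TPM 3 or 4 by pseudocount. The smallest edgeR adjusted p was 0.0831, for miR-223-3p, a miRNA of neutrophils and other myeloid cells. It had 1 count before DSS and 15 on day 5, a ratio of 32.8 (exact 95% interval 5.05 to 1382). Leaving out before-DSS library 4, which held the 1 count, it was 7.63-fold over the floor of 3 counts. The other miRNAs of smallest p with higher values were novel_249 (log2 fold change 3.27, and 4.28 without before-DSS library 3), miR-106b-3p (1.26), miR-146a-5p (1.66, and 0.96 without day 5 library 3), which restrains inflammatory signalling, and let-7i-5p (0.87). Those with lower values were miR-5126 (-2.78, and -4.06 without day 5 library 1), miR-122-5p and miR-122b-3p (-1.75 each, with identical counts), let-7c-5p (-1.15) and miR-3473a (-2.32). Of the 137 miRNAs, 21.2% (22 higher and 7 lower) had groups that did not overlap in CPM by library total and 18.2% (19 higher and 6 lower) with TMM factors, where chance gives 5.71%. Scaling by library total only, without composition factors, moved the median log2 fold change of all miRNAs by 0.38 in this comparison and gave 11 calls, all higher.

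The comparison of day 12 with before DSS asked what differed from the starting profile after recovery. By the same edgeR test 9 miRNAs were higher and 0 were lower. At an unadjusted p under 0.05 there were 17 higher and 6 lower, and DESeq2 called 10 higher and 2 lower. Each of the 9 had 4 of 4 recovery libraries above every before-DSS library. Of all 137 miRNAs, 13.9% (13 higher and 6 lower) had groups that did not overlap in CPM by library total, where chance gives 2.86%. With TMM factors it was 11.7% (12 higher and 4 lower). Members of the leukocyte list had the 4 largest distinct changes. miR-223-3p rose from 8.97 ± 17.9 CPM (SD, n = 4) to 4488 ± 1734 CPM (SD, n = 4), from 1 count to 480, a ratio of 392 (exact 95% interval 70.1 to 15532), with a fitted log2 fold change of 8.10 ± 0.73 (SE) and an edgeR adjusted p of 1.04e-05. Without before-DSS library 4, which held the 1 count, it was 91.2-fold over the floor of 3 counts (fitted log2 fold change 9.73). miR-223-5p, from the other arm of the same hairpin, had 0 counts before DSS. It had 86 on day 12, 23.4-fold over the floor of 3 counts (edgeR adjusted p = 0.00527). miR-142a-3p, a miRNA of blood cell lineages, had 0 counts before DSS, which allows up to 32.6 CPM. It had 103 on day 12, 28.1-fold over the floor of 3 counts (edgeR adjusted p = 0.00591). Leaving out recovery library 1, which held 63 of the counts, it was 17.1-fold over the floor. miR-142b had the same counts in every library as miR-142a-3p, and its hairpin overlaps that of miR-142a on the opposite strand, so the 9 calls stand for 8 distinct rows. miR-142a-5p rose by a log2 of 3.72 ± 0.83 (SE), from 7 counts to 130, and by 4.96 without before-DSS library 4 and 2.94 without recovery library 1.

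The other 4 miRNAs that rose were not members of the leukocyte list. miR-139-5p rose by a log2 of 3.42 ± 0.63 (SE), from 292 ± 217 to 3013 ± 1666 CPM (SD, n = 4 each). miR-652-3p rose by 2.10 ± 0.53, miR-146b-5p, a miRNA induced in inflammation, by 1.59 ± 0.41, and miR-744-5p by 1.21 ± 0.30 (log2, SE). The lower values of smallest p did not pass the threshold: miR-148a-3p had a log2 fold change of -1.40, miR-215-3p of -1.88, miR-122-5p and miR-122b-3p of -1.48 and miR-1a-3p and miR-1b-5p, with identical counts, of -1.37. miR-148a-3p and miR-215-3p did pass with the replicate block (edgeR adjusted p = 0.0129 and 0.00414), and they were the 2 lower calls there and with DESeq2. Both also passed with library totals only, with limma-trend at pseudocounts of 1 and 10, and without before-DSS library 2 or recovery library 1. miR-21a-5p had a log2 fold change of 0.85 (edgeR adjusted p = 0.346), and it was among the calls with library totals only. The count was 5 without before-DSS library 1, 6 without before-DSS library 3 or 4, 7 without recovery library 3 or 4 and 14 without before-DSS library 2, and miR-744-5p lost its call under 10 of 24 alternatives, miR-652-3p and miR-146b-5p under 6 each and miR-142a-5p under 2. It was 17 without a filter on low counts, 15 (13 higher and 2 lower, all 9 calls kept) with the column number as a replicate block, and 18 without before-DSS library 2 and recovery library 4. Before-DSS library 2 had a median correlation of 0.853 with its group, where the others had 0.964 to 0.966, and recovery library 4 lay at 15.2 on the first principal component, where the next highest library lay at 6.82.

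The hairpin of miR-223 lies on chromosome X at 96242817 to 96242926, in an exon of F630028O10Rik, annotated as an antisense RNA gene. That of miR-142a lies on chromosome 11 at 87756864 to 87756927 in an intron of Mir142hg. The hairpins of miR-139 (chromosome 7, 101475376 to 101475443), miR-652 (chromosome X, 142739000 to 142739097) and miR-744 (chromosome 11, 65734733 to 65734832) lie in introns of Pde2a, Tmem164 and Map2k4. The hairpin of miR-146b lies on chromosome 19 at 46342762 to 46342870 in an intron of Mfsd13a.

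**Figure D1:**
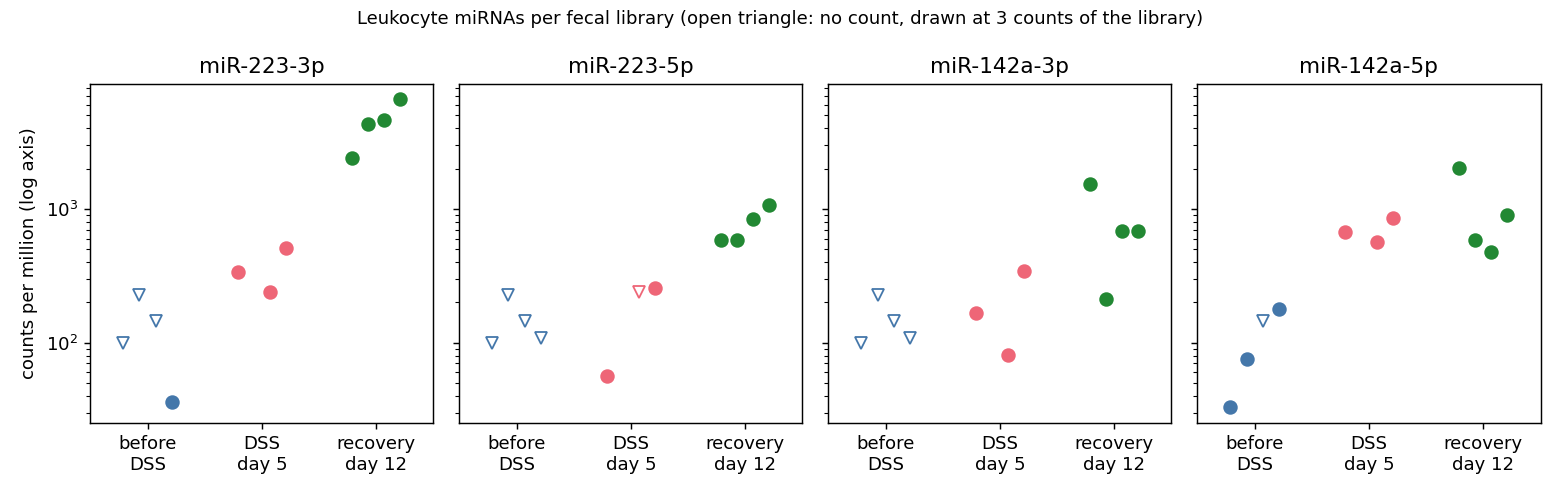
CPM (log axis) of 4 leukocyte miRNAs in each library of the 3 phases, with open triangles for libraries without a count, drawn at the value of 3 counts. For miR-223-3p each of the 4 recovery libraries lies above each day 5 library and each before-DSS library, the latter with 1 count in all.

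The comparison of day 12 with day 5 asked what differed between recovery and the acute phase. By the same edgeR test 4 miRNAs were higher and 1 was lower, and the groups did not overlap for any of them, except that those of miR-744-5p did in CPM by library total and not with TMM factors. Of all 137 miRNAs, 13.1% (6 higher and 12 lower) had groups that did not overlap in CPM by library total, where chance gives 5.71%. With TMM factors it was 16.1% (12 higher and 10 lower), so the balance of directions depended on the scaling. miR-223-3p rose by a log2 of 4.01 ± 0.59 (SE), from 362 ± 137 CPM (SD, n = 3) to 4488 ± 1734 CPM (SD, n = 4), with an edgeR adjusted p of 0.00192. miR-5126 rose by 3.01 ± 0.73, miR-652-3p by 2.82 ± 0.65 and miR-744-5p by 1.35 ± 0.34 (log2, SE). Without day 5 library 1 the value of miR-5126 was 4.30, and without day 5 library 4 that of miR-652-3p was 3.53. The numbered row novel_249 fell by 4.36 ± 0.90 on the log2 scale, from 1579 ± 996 (SD, n = 3) to 53.0 ± 49.4 CPM (SD, n = 4), with a log2 fold change of -5.02 without recovery library 4. Next by p were miR-223-5p (log2 fold change 3.30, edgeR adjusted p = 0.0692, and 4.67 without day 5 library 4), and with lower values miR-10b-5p (edgeR adjusted p = 0.0878), miR-146a-5p (-1.58, and -0.88 without day 5 library 3), let-7i-5p (-0.82) and miR-106b-3p (-0.94). Of 23 alternatives, miR-223-3p lost its call under 2, miR-5126 under 10, miR-652-3p under 11 and miR-744-5p under 15, and novel_249 under 7 of 21. The count was 1 without day 5 library 4, recovery library 2, recovery library 3 or the numbered rows, 2 without day 5 library 1 or 3, 2 with library totals only, which moved the median log2 fold change by -0.34, and 0 with limma-trend at pseudocounts of 1 and 0.1. The replicate block gave 14 calls (12 higher and 2 lower), which kept all 5 and added miR-142a-3p (edgeR adjusted p = 0.0300), miR-223-5p (0.0288), miR-378a-3p (0.0288) and miR-21a-5p (0.0332) among others, DESeq2 gave 12 and no filter gave 21.

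**Figure D2:**
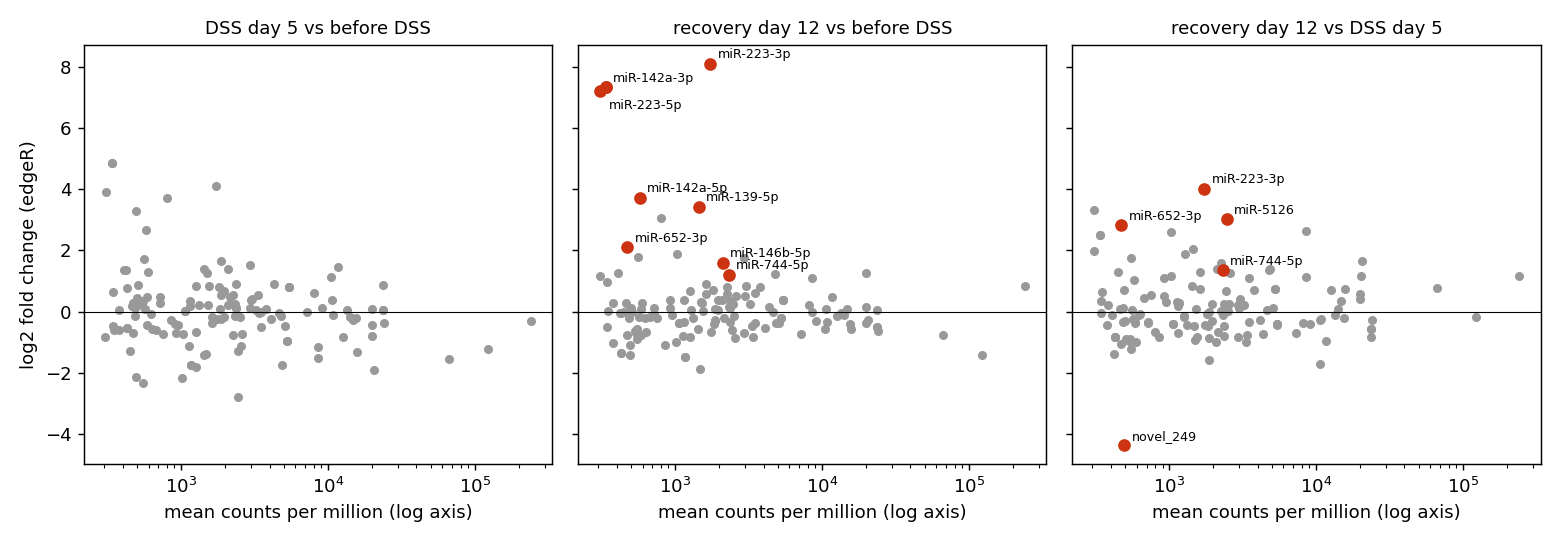
Log2 fold change from edgeR against mean CPM over the 11 libraries (log axis) for 137 miRNAs in each of the 3 comparisons, with red points for miRNAs past the threshold and grey points for the rest. Red points number 0, 9 and 5, and miR-142b lies under miR-142a-3p.

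A test for any difference among the 3 phases called 11 miRNAs: the 9 that rose between before DSS and day 12, miR-5126 and novel_249. Its count was 7 without before-DSS library 1, before-DSS library 3 or day 5 library 3, and 22 with the replicate block. miR-142a-3p had 0 counts in 92108 before DSS, 8 in 42075 on day 5 and 103 in 112664 on day 12. On day 5 it was 5.84-fold over the before-DSS floor of 3 counts, and 3.91-fold without before-DSS library 1. The counting error of the 8 counts is left out of these folds. Its edgeR adjusted p for day 5 against before DSS was 0.155. Between day 12 and day 5 its log2 fold change was 2.49 ± 0.88 (SE), with an edgeR adjusted p of 0.157. Exact two-sided permutation tests of log2(CPM + 1) gave p = 0.0286 for day 12 against before DSS, the smallest that 4 against 4 libraries allow, p = 0.0571 for day 5 against before DSS, the smallest that 3 against 4 allow, and p = 0.114 for day 12 against day 5. Adjusted over these 3 exact tests they were 0.0857, 0.0857 and 0.114.

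The leukocyte list had 4 tested members of 8 (miR-223-3p, miR-223-5p, miR-142a-3p and miR-142a-5p) and was higher in each comparison by camera. These are arms of 2 hairpins. The 4 members below the filter had at most 17 counts in a phase: miR-342-3p stood at 173 CPM before DSS, 163 on day 5 and 109 on day 12, miR-29c-3p at 67.6, 28.4 and 49.0, miR-150-5p at 28.6, 196 and 190.5, and miR-155-5p at 0 counts, 56.7 and 73.6 CPM. Its adjusted p was 0.00142 for day 5 against before DSS, 2.05e-10 for day 12 against before DSS and 0.00120 for day 12 against day 5. With an estimated correlation the camera adjusted p was 0.240, 0.0295 and 0.237, so the call held between day 12 and before DSS only, and there not without before-DSS library 2 (0.130) or recovery library 1 (0.204). All 4 tested members were higher on day 12 than before DSS. With the miRNAs without counts before DSS set against the floor of 3 counts, the median log2 fold change was 4.68. Before DSS these 4 had 1, 0, 0 and 7 counts, so the filter on low counts kept them only because of the later groups. Members that did not rise had less chance of being tested. That all 4 were higher, and the camera calls, therefore rest in part on this filter. On day 5 against before DSS 0 of 4 members passed over all miRNAs and 4 adjusted over the list alone. On day 12 against day 5 it was 1, and 3 adjusted over the list alone. The colitis-responsive list was higher on day 12 than before DSS (adjusted p = 0.00809 by camera), with miR-223-3p and miR-146b-5p past the threshold and miR-21a-5p, miR-7a-5p and miR-146a-5p not. With an estimated correlation its camera adjusted p was 0.132. It shares miR-223-3p with the leukocyte list. Its adjusted p was 0.244 on day 5 against before DSS and 0.136 on day 12 against day 5 by camera, and adjusted over the list alone 2 members were higher on day 5 against before DSS, and 3 higher and 1 lower on day 12 against day 5.

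No other list passed in any of the 27 camera tests. The 4 tested rows of the erythroid list, miR-451a, which is abundant in red blood cells, and 3 rows of miR-486 with nearly equal counts, had a median log2 fold change of 0.81 on day 5 against before DSS (adjusted p = 0.136 by camera). Leaving out recovery library 4 alone, the erythroid list was higher on day 5 than before DSS (camera adjusted p = 0.00966) and lower on day 12 than on day 5 (0.000265), and leaving out day 5 library 3 it was higher on day 5 (0.0478). With an estimated correlation these camera adjusted p were 0.473, 0.223 and 0.805, so none of the 3 calls held. miR-451a stood at 6706 ± 2097 CPM (SD, n = 4) before DSS, 22628 ± 6729 (SD, n = 3) on day 5 and 8642 ± 5377 (SD, n = 4) on day 12. The intestinal epithelium list had a median of -0.80 on day 5 and -0.38 on day 12 against before DSS (camera adjusted p = 0.136 and 0.255), with log2 fold changes of -1.23 and -1.40 for miR-148a-3p, -1.55 and -0.77 for miR-192-5p (-2.32 on day 5 without day 5 library 1), -0.42 and 0.16 for miR-194-5p, and -0.80 and -0.38 for miR-215-5p. Leaving out day 5 library 1, it was lower on day 5 (camera adjusted p = 0.0272, and 0.546 with an estimated correlation). Adjusted over the list alone, 1 of its 5 members was lower on day 12 than before DSS. The miR-200 family, miRNAs of epithelial cells, had a median of -0.75 on day 5 and 0.52 on day 12 against before DSS (camera adjusted p = 0.211 and 0.721), with log2 fold changes of 0.10 and 1.27 for miR-200b-3p (0.56 on day 12 without recovery library 4), -1.31 and -0.56 for miR-200a-3p, -0.14 and 1.21 for miR-200c-3p, and -0.75 and 0.52 for miR-429-3p. The miR-17-92 and paralogous clusters had a median of 0.71 on day 5 (adjusted p = 0.136 by camera), with 0.89 for miR-25-3p, 0.60 for miR-92a-3p, 0.83 for miR-93-5p and -0.08 for miR-20a-5p.

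The let-7 family (9 tested members), the miR-30 family (5) and the neuronal list (4) had median log2 fold changes within -0.30 and 0.01 of the starting profile on days 5 and 12, with camera adjusted p of at least 0.360. On day 5 the direction of the camera test was the opposite of the sign of the median for the miR-30 and neuronal lists. miR-9-5p, best known from neural tissue, stood at 23942 ± 13789 CPM (SD, n = 4) before DSS, and miR-124-3p at 628 ± 337 CPM. Before-DSS libraries 1 to 4 held 593, 572, 462 and 296 counts of miR-9-5p. Their totals were 30418, 13240, 20580 and 27870, so these counts did not follow the totals. The cause was not tested. The miR-183 cluster, smooth muscle and stroma, squamous epithelium, endothelium, striated muscle, liver and miR-29 family lists had 2 or 1 tested members and no set test. Of these, miR-182-5p, miR-183-5p, miR-143-3p, miR-199a-3p, miR-203-3p, miR-126a-3p, miR-1a-3p, miR-122-5p and miR-29a-3p had log2 fold changes on day 12 against before DSS of -0.38, 0.59, -0.73, -0.70, -0.79, 0.14, -1.37, -1.48 and 0.06. None of these passed the threshold over all 137 miRNAs. The unadjusted edgeR p of miR-122-5p, a miRNA of liver, was 0.0147 on day 5 and 0.0172 on day 12 against before DSS, and that of miR-1a-3p was 0.0448 on day 12. The pancreas and miR-34 family lists had 0 tested members.

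As a share of all miRNA counts, the leukocyte list made up 0.0351% ± 0.00887 (SD, n = 4) before DSS, 0.180% ± 0.0666 (SD, n = 3) on day 5 and 0.745% ± 0.143 (SD, n = 4) on day 12. Each recovery library lay above each day 5 library, and each day 5 library above each before-DSS library. The erythroid list made up 1.88% ± 0.932, 4.77% ± 1.11 and 2.26% ± 1.48 in the same order, and the intestinal epithelium list 32.6% ± 8.03, 19.0% ± 6.80 and 17.1% ± 4.14. The erythroid share adds up 3 rows of miR-486 with nearly equal counts, which may repeat the same reads and so raise the share. The top miRNA took 19.3% ± 2.81 of the counts before DSS and 32.8% ± 8.05 on day 12. For the leukocyte share and the share of the top miRNA, exact two-sided permutation tests of day 12 against before DSS each gave p = 0.0286, the smallest possible, and 0.171 after adjustment over the 24 composition tests, of which none passed after adjustment or could have. The number of miRNAs with a count was 308.5 ± 18.2 before DSS, 300.0 ± 7.00 on day 5 and 333.5 ± 43.8 on day 12, and thinned to 11749 counts it was 259.2, 287.4 and 264.8. The Shannon entropy was 4.95, 5.43 and 4.85 bits.

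**Figure D3:**
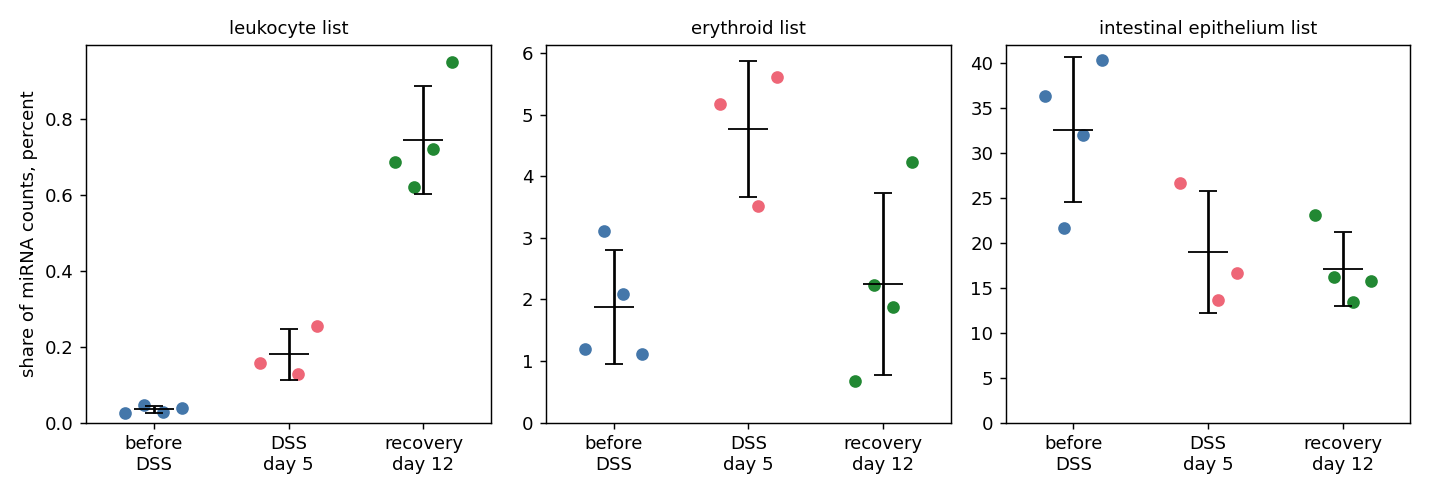
Share of miRNA counts (percent) of the leukocyte, erythroid and intestinal epithelium lists in each library of the 3 phases, with the group mean and SD in black. The leukocyte share separates the 3 phases without overlap, and the mean erythroid share is 4.77% on day 5. The erythroid share adds up 3 rows of miR-486 with nearly equal counts, which may repeat the same reads.

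The changes on day 5 and on day 12 against the same before-DSS libraries had a correlation of 0.463 across the 137 miRNAs, which are not independent replicates. Simulated unchanged groups against those libraries gave a mean of 0.457 (SD 0.0862 over 100 simulations). The covariance was 0.414 against a simulated mean of 0.136 (SD 0.0351, highest 0.223), a difference of 0.278. The changes also spread more widely than the simulated ones. Their SD across miRNAs was 0.87 against 0.57 on day 5 and 1.03 against 0.52 on day 12. Of the miRNAs, 61.3% had the same sign in both, against 65.0% simulated. The higher covariance thus went with the wider spread and does not show a shared change beyond the controls. With the 4 before-DSS libraries split in 2 and 2, so that the changes share no library, the correlation was 0.318 on average and ranged from 0.214 to 0.433. Since day 5 had 0 calls, the overlap of calls was 0.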

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

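The tests of other splits for the 3 pairwise comparisons and within column numbers and the tests on depth and blood were chosen only after the results had been seen. In 7 of 76 groups of 4 libraries tested, where chance gives about 3.8, 1 library lay far from the other 3 relative to the range of the group. Before DSS, library 4 held the only count of miR-223-3p (35.9 CPM against 0 in the others). Library 1 had 3057 CPM of miR-122-5p, and of miR-122b-3p with the same counts, against a median of 1435 CPM in the others. Library 2 had 24925 CPM of miR-200b-3p (median of the others 9580), 1360 CPM of miR-215-3p (2827) and 4079 CPM of miR-10b-5p (2430). In the recovery group, library 4 had 31191 CPM of miR-194-5p (17748).

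Leukocyte miRNAs from 2 hairpins were higher on day 12. With all libraries thinned to the smallest total, the lowest recovery library had 13.5 times the leukocyte share of the highest before-DSS library. Thinning leaves the expected share of a list unchanged, so this value could not test the deeper recovery libraries as the cause. If blood of fixed composition were the only source of both lists, leukocyte and erythroid miRNAs would have kept 1 ratio. The median ratio was instead 9.04 times higher on day 12 than on day 5. Each recovery library (0.225 to 1.02) lay above each day 5 library (0.0302 to 0.0455). An exact two-sided permutation test of the log2 ratio gave p = 0.0571, the smallest possible. The ratio was chosen after the values of both lists had been seen, so it is no independent test. Other sources of either list were not tested. The erythroid counts in this ratio include rows of miR-486 with nearly equal counts, so its level depends on whether these repeat the same reads. The phase of the disease, such as leukocytes in the gut on day 12, may account for the rise and remains an untested hypothesis. No library came from untreated mice on day 5 or 12. Phase therefore cannot be told apart from the day of sampling or from anything that changed with it. Of the leukocyte members that did not pass the filter, miR-342-3p had 13 counts before DSS and 11 on day 12, with a lower mean on day 12 (109 against 173 CPM). The mean of miR-29c-3p was also lower (49.0 against 67.6 CPM). Higher means on day 12 were those of miR-150-5p (3 counts before DSS and 17 on day 12) and miR-155-5p (0 and 9). Open too is a change in the makeup of the blood itself.

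Other splits of the libraries were counted for each test across miRNAs. For day 5 against before DSS the real count was 0, which all 35 splits reach (highest other 0), so this count tests nothing. For recovery against before DSS 2 of 35 splits gave as many as the real 9, and the other one gave 10, so chance is not excluded by this count. That split set before-DSS libraries 1, 3 and 4 with recovery library 1 against the rest and shared 1 call with the real split, which points to a structure of the libraries other than phase. Among the 8 splits that part all pairs of equal column number, the real one gave 9 and the highest other 0, and 8 splits are too few for a share under 0.05. For recovery against day 5 the real split alone, 1 of 35, gave 5 calls and the highest other gave 2. This share is under 0.05 and the smallest that 35 splits allow, and it was not adjusted over the split tests. Among the 8 that part all 3 pairs the real one gave 5 and the highest other 0, again too few for a share under 0.05. For any of the 3 phases 1 of 100 random splits, the real one, gave 11, and the highest other gave 9. Of 100 splits that exchange phases only among libraries of the same column number, 1, the real one, gave 11, and the highest other gave 7. Both shares are under 0.05 and the smallest that 100 splits allow. They were not adjusted over the split tests, so chance is made less likely but is not excluded. Of the list tests, 29 of 100 random splits gave as many as the real 4, with a highest other of 9, and 42 of 100 within column numbers, with a highest other of 8, so the number of list calls does not exceed chance. The leukocyte list passed in all 3 comparisons in 3 of 100 splits, the real one included, with a highest other of 3, a share under 0.05. Within column numbers it was 5 of 100, also with a highest other of 3, so chance is not excluded there. The list passed in at least 1 comparison in 48 of the other random splits, and with an estimated correlation 2 of the 3 calls were lost (camera adjusted p = 0.240 on day 5 against before DSS and 0.237 on day 12 against day 5).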

How the results depend on the processing

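Among the tested miRNAs, 1 that passed under an alternative had the opposite direction in the fit of all libraries: miR-3470a, recovery against before DSS, was 1.68 without before-DSS library 2 and 1.74 without it and recovery library 4, against -0.59 with all. Among 1377 values of the singly named miRNAs under alternatives 26 had another sign, in 11 results, with 0 past the threshold. Of lists short of the threshold, the neuronal and miR-30 lists (day 5 against before DSS), the erythroid, miR-17-92 and miR-200 lists (day 12 against before DSS) and the epithelium list (day 12 against day 5) changed direction when single libraries were left out, and the neuronal list also with RLE factors and the replicate block. Of 1383 values of 66 singly named results under alternatives, 1195 kept their side of the threshold or moved by less than the spread, 58 newly passed, 69 no longer passed and 61 moved. Merging rows, leaving out numbered rows, leaving out before-DSS library 2 with recovery library 4 and leaving out each library in the list tests, also with an estimated correlation, were chosen after the data were seen. The cause of each change below was not tested unless the setting itself tests fewer or more miRNAs or samples. Totals of 11749 to 40835 counts limit all comparisons.

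Between recovery and before DSS, miR-223-3p, miR-223-5p, miR-142a-3p and miR-139-5p passed under each alternative, and miR-142b wherever it was not merged with miR-142a-3p, while miR-744-5p was lost under 10 of 24 and miR-652-3p and miR-146b-5p under 6 each. The count of 9 was 17 without a filter on low counts, 15 with the replicate block, 18 without before-DSS library 2 and recovery library 4, and 5 to 14 when each library was left out. Between recovery and day 5, the count of 5 was 2 with library totals only, 21 without a filter, 10 with at least 10 CPM in at least 3 libraries (a filter that kept 412 rows), 12 with DESeq2, 0, 0 and 1 with limma-trend on TPM (pseudocounts 1, 0.1 and 10), 2 with only the groups compared, 14 with the replicate block, 1 without numbered rows, 10 without before-DSS library 2 and recovery library 4, and 1 to 7 when each library was left out. miR-223-3p was lost there under 2 of 23 and miR-744-5p under 15.

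Between day 5 and before DSS, the count of 0 was 11 with library totals only, 15 without a filter, 5 with at least 10 CPM in at least 3 libraries, 5 with DESeq2, 3, 3 and 4 with limma-trend, and 0 when each library was left out. The replicate block gave 16 (5 higher and 11 lower) and called the intestinal epithelium list lower (camera adjusted p = 0.0221). Whether column numbers pair these libraries was not clear. The pairs correlated at 0.10, 0.13 and -0.10, and 1 of 3 correlated best with its own number, so the blocked calls stay open. For any of the 3 phases, the count of 11 was 29 without a filter, 17 with at least 10 CPM, 23 with DESeq2, 4 with limma-trend at pseudocounts 1 and 0.1, 22 with the replicate block, and 7 to 11 when each library was left out.

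For miR-142a-3p, the log2 fold change of 4.84 on day 5 against before DSS was 5.18 with library totals only, 4.84 without a filter, 7.39, 10.70 and 4.15 with limma-trend and 4.60 with the replicate block, all past the threshold, 2.81 with limma-voom, not past it, and 4.38 to 5.25 when each library was left out. Between recovery and day 5, 2.49 became 2.59 without a filter and 2.79 with the replicate block, both past the threshold, and 1.75 to 2.99 when each library was left out. Between recovery and before DSS it was 6.53 to 7.70 when each was left out. Against a group of 0 counts these fitted values depend on the prior count or pseudocount and are no bounds. Against the floor of 3 counts the log2 fold was 2.55 on day 5 and 4.81 on day 12. These 2 values leave out the counting error of the later counts.

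Of the 4 list calls, 1 held with an estimated correlation, and 4 to 6 passed when each library was left out, or 0 to 1 with an estimated correlation as well (0 without before-DSS library 2 or recovery library 1). The replicate block changed no other list call. The correlation of day 5 and day 12 changes, 0.463, was 0.318 with split controls and 0.589 without before-DSS library 2 and recovery library 4. No composition test passed in any setting, and none could.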

Other observations

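The tests on libraries that stand apart and on rows with nearly equal counts were chosen after the data were seen. Other miRNAs varied between single libraries. miR-184-3p had 519 counts in recovery library 2 and 1 to 12 in each of the other libraries. The numbered row novel_214 had 326 counts in day 5 library 4, 82 in recovery library 1 and at most 5 in each of the other libraries, and novel_401 had 158 counts in recovery library 4 and 0 in the others. miR-9-5p had 24 counts in recovery library 4 and 296 to 780 in each of the others. Recovery library 4 also held 8 counts of miR-100-5p (at least 120 in each of the others), 0 of miR-218-5p (at least 23) and 6 of miR-99b-5p (at least 47). It held 1453 of miR-200b-3p, against 101 to 625 in each of the others. The first principal component, where this library lay at 15.2, had 37% of the variance and the second 22.7%. What sets it apart on the first was not tested. miR-16-5p, chosen after its values were seen, stood at 1142 ± 213 CPM (SD, n = 4) before DSS, 4314 ± 2154 (SD, n = 3) on day 5 and 3731 ± 1624 (SD, n = 4) on day 12, with edgeR adjusted p of 0.164 and 0.0788 against before DSS. On day 12 it passed under 11 of 24 alternatives, among them the replicate block (edgeR adjusted p = 0.0128) and DESeq2 (0.0181), and on day 5 under 1 of 23, library totals only (edgeR adjusted p = 0.0462).

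Libraries stood apart within their groups. In the second principal component of the 137 miRNAs, scaled by library total, before-DSS library 2 lay with the DSS libraries (0.83) and away from before-DSS libraries 1, 3 and 4 (-9.10, -6.60 and -8.20). With TMM factors, the scaling of the components in the report, it lay at -3.03 and libraries 1, 3 and 4 at 6.98, 4.82 and 7.62. The recovery libraries grouped differently by scaling: 0.52, 5.33, 6.59 and 6.77 for libraries 1 to 4 by library total, and 3.48, -5.33, -5.40 and 0.09 with TMM factors. After thinning to 1 depth the component correlated with the original at 0.990, so it was kept when the totals were equal. Thinning leaves expected shares unchanged and does not remove the counting error of the libraries with few counts. Whether few counts in some libraries account for how the libraries stood apart therefore could not be decided by this value. A different share of RNA from intestinal epithelium may account for how the libraries stood apart. With the 5 list members left out, the component followed the epithelial share with Pearson's r = 0.906 (permutation p = 0.00025, adjusted 0.00075 over 3 relations). Spearman's rho was 0.773 (permutation p = 0.00709) over 11 libraries. The totals used for scaling still held the list members, so part of this relation may come from the scaling itself. Without the 2 libraries farthest from the median share r was 0.788. With group means taken out r was 0.771 (permutation p = 0.0246, adjusted 0.0369) and rho 0.682 (permutation p = 0.0339), and 0.536 without the 2 farthest libraries. With TMM factors and totals taken without the list members, r was 0.881 (permutation p = 0.00048) and rho 0.845. With group means also taken out, r was 0.839 (permutation p = 0.00216). Each phase holds too few libraries for a correlation of its own.

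Rows with nearly equal counts came in 12 pairs, counted where the summed difference was at most 5% and the rows held at least 50 counts. Of 8 pairs with both hairpins annotated, 7 (87.5%) overlapped on opposite strands, against 3 of 11927 other pairs. Of 10 pairs of rows with hairpins on opposite strands, 7 had nearly equal counts. Counting that ignores the strand may therefore explain miR-142b, miR-1b-5p, miR-129b-3p, miR-374c-3p, miR-3071-5p, miR-3074-5p and miR-3074-2-3p, which then repeat reads of their partners. The pairs of miR-9-5p with miR-9b-3p, of miR-122-5p with miR-122b-3p and of miR-486b-3p with both arms of miR-486a had a hairpin without an entry in the annotation used here and remain open.

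The numbered rows made up 0.326% ± 0.0271 of the counts before DSS (SD, n = 4), 2.05% ± 1.83 on day 5 (SD, n = 3, with a mean of 0.996% without day 5 library 4, which had 4.16%) and 0.742% ± 0.128 on day 12 (SD, n = 4). This share was looked at after the data were seen. Exact two-sided permutation tests gave an adjusted p of 0.0571 in each of the 3 comparisons.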
